A study of Mus musculus with 64 samples.

How the data were processed

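Gene expression was measured in 64 RNA samples from 4-month-old Tg2576 and wild-type mice that received vehicle or PF-04447943, an inhibitor of the phosphodiesterase encoded by Pde9a, for 28 days by implanted pump. Each of the 8 groups, made of a genotype, a treatment and a brain region, held 8 samples, and each sample was hybridised to its own Affymetrix mouse array with 45101 probe sets. The values used were the deposited intensity values, which the authors had made with RMA per the submitters' processing notes. The RMA software and its version are not given in the sources used here. RMA usually corrects the background, makes the distributions of the arrays equal and summarises the probes of a probe set. The interquartile range of the deposited log2 values still ran from 3.37 to 3.90 between arrays, and whether all arrays were normalized together or run in batches is not known. The deposited values ran from 5.87 to 34088.93, a linear scale, and were converted to log2. Raw array images were not processed again. Arrays have no read depth, so the 8 arrays of a group limit the precision.

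Gene names came from a table of mouse RefSeq genes, used for names and chromosomes of the GRCm38.p6 assembly. Of the probe sets, 34957 had 1 gene symbol, 920 had several symbols, 9160 had none there and 64 were controls. Each of 18201 genes was represented by its probe set with the highest mean over all 64 arrays. Genes whose mean lay below the 40th percentile of the probe sets of a region, log2 5.94 in hippocampus and 5.91 in prefrontal cortex, were left out. This left 12962 genes tested in hippocampus, 12926 in prefrontal cortex and 12951 over both regions. Genes without a probe set of their own under this naming were not analysed here.

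Differences were estimated with limma 3.58.1 in R 4.3.3 with data.table version 1.17.8, with 4 groups in 1 fit per region and 8 groups in 1 fit over both regions. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. By chance an unadjusted p under 0.05 is expected for 648.1 genes in hippocampus, 646.3 in prefrontal cortex and 647.55 over both regions. In each region the transgene effect was tested under vehicle, under PF-04447943 and averaged over both treatments. The drug effect was tested in Tg2576 mice, in wild-type mice and averaged over both genotypes, and the drug by genotype interaction was tested as well. Over both regions, the drug effect by region, the transgene effect by region and the regional difference in vehicle-treated wild-type mice were tested. The main fits used no pairing, because the labels do not state that a replicate number marks 1 mouse. Over 23 probe sets with 2 separate levels, every hippocampal array matched a prefrontal cortex array of its own group, 26 of 32 with its own number. Fits on these matched mice, and fits by replicate number, were alternatives for the comparisons of both regions.

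Before the data were examined, 40 gene lists were fixed, 18 of cell type markers and 22 of pathways and gene groups. Each list with at least 5 tested genes was tested with camera of limma at its preset inter-gene correlation of 0.01, with adjustment over the lists of 1 comparison. Camera with a correlation estimated for each list, and the rotation test fry, were alternatives. The named genes were also chosen by a rule fixed beforehand. It took the 10 largest rises and the 10 largest falls in log2 value among genes past the threshold, or the 5 genes with the smallest p where fewer than 5 passed. It added Pde9a, every probe set of App and Prnp, up to 4 members past the threshold of each list, and for the regional difference the members of each list that changed most. Other genes named were chosen after their values were seen.

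The mean log2 value of the cholesterol synthesis and uptake list was computed per array and compared between groups with two-sided permutation tests, exact with 12870 regroupings for 8 against 8 arrays, and sampled with 1e+05 resamples within treatment or genotype for averaged effects. These tests, the interquartile range of the log2 values of each array as a measure of signal range, and the comparison of replicate numbers 1 to 4 with 5 to 8 were added after the data had been seen. The array figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

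The alternatives planned beforehand were no filter or a 60th percentile filter, all probe sets tested separately, the mean of the probe sets of a gene, quantile normalization within the region, and centring of each array on its median. Further ones were a mean-variance trend with a robust prior, array weights, covariates for RNA quality and for dissection, a fit of only the compared groups, replicate number as a block, an adjusted p threshold of 0.10, and each array left out in turn. The RNA quality covariate was the mean 3 prime minus 5 prime log2 difference of the Actb and Gapdh control probe sets. The dissection covariate was the mean standardised level of choroid plexus markers in hippocampus and of striatal markers in prefrontal cortex. A sex covariate was not run, since Xist was high on all 64 arrays, from log2 11.54 to 12.75. The limma procedure was tested on simulated data with group sizes and spreads like those measured. A simulated log2 change of 0.5 was recovered in 82% of genes for 8 against 8 hippocampal arrays and in 88% for prefrontal cortex. A change of 0.25 was recovered in 46% and 38%. The simulated noise was independent between genes, while measured arrays of a group share variation. Changes of log2 1 and larger were simulated along with these, which eases the adjusted threshold. The shares can therefore be too high for the measured data.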

Results

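The series measured RNA from hippocampus and prefrontal cortex of Tg2576 mice, which carry a human amyloid precursor protein transgene driven by prion protein gene sequences, and of wild-type mice. Mice of both genotypes received vehicle or PF-04447943, an inhibitor of the cyclic GMP-degrading enzyme Pde9a, for 28 days. Each of the 8 groups held 8 samples on 8 arrays. Group means of the median array intensity lay between 94.0 and 97.4. The lowest correlation of log2 values between a pair of arrays of 1 region was 0.974. The signal range, the interquartile range of an array's log2 values, moved with the drug in hippocampus. In wild-type hippocampus it was 3.51 ± 0.08 (SD, n = 8) under vehicle and 3.65 ± 0.06 (SD, n = 8) under PF-04447943, a difference of 0.13 (exact permutation p = 0.00311, adjusted p = 0.022). In Tg2576 hippocampus the difference was 0.085 (exact permutation p = 0.166, adjusted 0.398).

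What the transgene alters in hippocampus was examined by comparing Tg2576 with wild-type mice over both treatments. Genes of cholesterol synthesis were higher in Tg2576 mice. Stard4, which carries cholesterol between membranes, rose by 0.53 ± 0.07 on the log2 scale (SE, n = 16 per genotype, adjusted p = 0.000164), and Fdft1, squalene synthase, rose by 0.48 ± 0.06 (SE, adjusted p = 0.000164). Both were above the wild-type mean of their treatment on 16 of 16 Tg2576 arrays. Hmgcs1, an early enzyme of the pathway, rose by 0.34 ± 0.05 (SE, adjusted p = 0.000164), in 16 of 16 arrays. Sqle, squalene epoxidase, rose by 0.41, Nsdhl by 0.30 and Hsd17b7 by 0.27, each in 15 of 16 arrays.

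All 6 genes that rose are enzymes or carriers of the sterol pathway by textbook knowledge, and 5 of them belong to the fixed list of cholesterol synthesis and uptake. Of its 17 measured members, 5 rose past the threshold over all genes, 15 rose adjusted over the list alone, and 17 lay above 0. Among the members that missed the threshold over all genes, Fdps was at 0.34 (adjusted p = 0.0592) and Srebf2, the transcription factor that controls the pathway, at 0.18 (adjusted p = 0.0616). The list's mean difference was 0.24 (camera adjusted p = 1.53e-31; adjusted p = 0.0038 with an estimated correlation). A permutation test within treatment gave p = 1e-05, the smallest these resamples can give (adjusted p = 0.00012 over 12 tests). The mean level of the list was 9.49 ± 0.16 in vehicle-treated Tg2576 mice and 9.24 ± 0.10 in vehicle-treated wild-type mice (SD, n = 8 each).

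**Figure D1:**
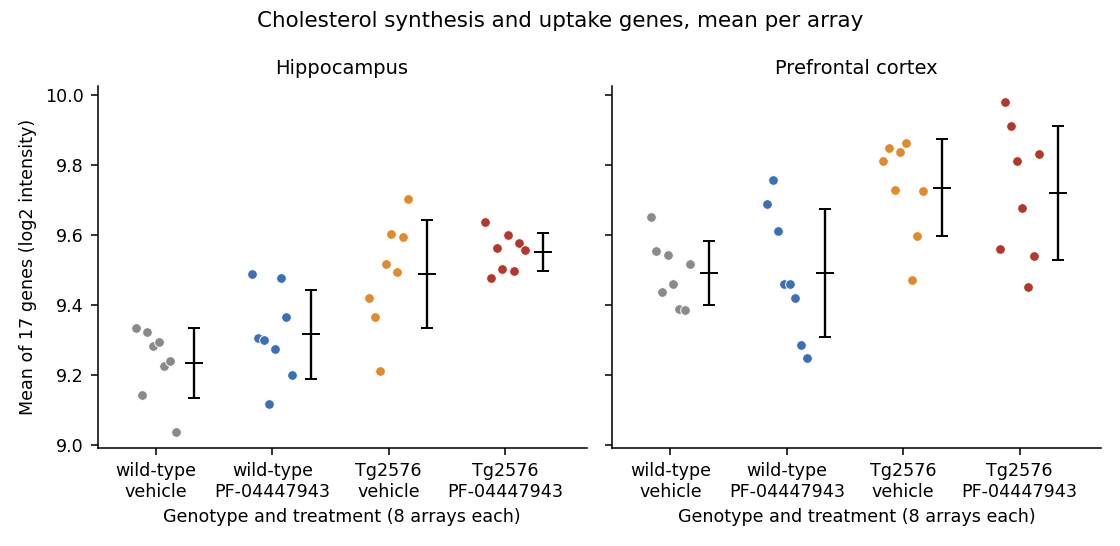
Mean log2 intensity of the 17 cholesterol synthesis and uptake genes on each of the 64 arrays, by region and group, with the group mean and SD. In both regions the Tg2576 group means, 9.49 and 9.55 in hippocampus and 9.74 and 9.72 in prefrontal cortex, lie above those of the wild-type groups.

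Another 6 hippocampal genes were lower in Tg2576 mice. Ogn, which encodes the extracellular matrix protein osteoglycin, fell by 0.85 ± 0.17 (SE, adjusted p = 0.0227, lower in 15 of 16 arrays). Dio2, the enzyme of astrocytes that activates thyroid hormone, fell by 0.46 ± 0.07 (SE, adjusted p = 0.00152, 16 of 16), and Npnt, a matrix protein, fell by 0.43 (adjusted p = 0.00284, 16 of 16). D16Ertd472e fell by 0.26, the innate immune receptor Tlr3 by 0.24 and the kinase Stk4 by 0.23, in 14, 15 and 16 of 16 arrays. Leaving out the array of wild-type PF-04447943 replicate 4 left 7 genes past the threshold in place of 12, leaving out wild-type vehicle replicate 1 gave 21, and leaving out Tg2576 vehicle replicate 5 gave 19. The count was 25 with array weights, of which 16 fell, 26 with all probe sets tested, 20 with the 60th percentile filter and 25 with signal range as a covariate, added after seeing the data. With the mean of probe sets it was 8, of which 6 rose and 2 fell, and the calls for Dio2, D16Ertd472e, Tlr3, Stk4 and Hsd17b7 ended, at -0.30, -0.17, -0.20, -0.057 and 0.16. With the 8 arrays per genotype numbered 1 to 4, chosen after seeing the data, 6 genes passed, of which 1 belonged to the 12.

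Cell type markers moved with genotype in hippocampus by the camera test at its preset correlation, and none of these calls held with an estimated correlation. Astrocyte markers fell, with a mean of -0.10 and 2 of 13 members lower adjusted over the list alone (camera adjusted p = 1.26e-05; adjusted p = 0.326 with an estimated correlation). Dentate granule cell markers fell, mean -0.33 (camera adjusted p = 3.2e-06; adjusted p = 0.345 with an estimated correlation), as did oligodendrocyte and myelin markers, mean -0.16 (camera adjusted p = 4.63e-05; adjusted p = 0.731 with an estimated correlation). Without Tg2576 PF-04447943 replicate 1, the array of its group lowest in oligodendrocyte and myelin markers, the mean of these markers was -0.086. That of dentate granule cell markers was then -0.23. Microglial markers had a mean of 0.05 (camera adjusted p = 0.0113; adjusted p = 0.877 with an estimated correlation), and 0.03 without Tg2576 vehicle replicate 6. No member of these 4 lists passed over all genes by limma, and 7, 7, 3 and 2 of them had an unadjusted p under 0.05.

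Under vehicle alone, Fdft1 was the single hippocampal gene past the threshold. It rose by 0.56 ± 0.09 in Tg2576 mice (SE, n = 8 per group, limma adjusted p = 0.00622), a fold of 1.48, in 8 of 8 arrays. Stard4 at 0.51, Sqle at 0.44 and Hmgcs1 at 0.32 missed it, with a limma adjusted p of 0.105 for Hmgcs1. The cholesterol list had 1 gene past the threshold, 10 adjusted over the list alone and a mean of 0.25 (camera adjusted p = 1.54e-24; adjusted p = 0.0163 with an estimated correlation; exact permutation p = 0.00218). In this pair of groups choroid plexus markers were lower in Tg2576 mice, with a median of -0.77 over 9 genes (camera adjusted p = 0.00429; adjusted p = 0.926 with an estimated correlation), and their mean went from -0.73 to -0.39 without wild-type vehicle replicate 5. The count of genes was 9 with replicate numbers 5 to 8 only and 0 with numbers 1 to 4, an alternative chosen after seeing the data, and 8 without Tg2576 vehicle replicate 3. The list's mean was 0.40 and 0.11 in those sets.

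Under PF-04447943, no hippocampal gene differed between genotypes past the threshold by limma, and 648 had an unadjusted p under 0.05, against 648.1 expected by chance. The cholesterol list again had all 17 members above 0, with a mean of 0.24 and 11 past the threshold adjusted over the list alone (camera adjusted p = 1.73e-19; adjusted p = 0.0516 with an estimated correlation; exact permutation p = 0.000466, adjusted 0.00186). Its members Stard4 and Hmgcs1 lay at 0.55 and 0.35, with a limma adjusted p of 0.0528 each. The mean level of the list was 9.55 ± 0.06 in Tg2576 and 9.32 ± 0.13 in wild-type mice (SD, n = 8 each).

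In prefrontal cortex the same question gave genes of the same pathway. Over both treatments 6 genes rose and 0 fell in Tg2576 mice, each in 15 of 16 arrays, and all 6 belong to the cholesterol list. Fdps, which makes farnesyl diphosphate, rose by 0.45 ± 0.08 (SE, n = 16 per genotype, adjusted p = 0.016). Sqle rose by 0.38 ± 0.07 (SE, adjusted p = 0.0135) and Fdft1 by 0.37 ± 0.06 (SE, adjusted p = 0.0129). Stard4 rose by 0.38, Msmo1 by 0.33 and Nsdhl by 0.29, with adjusted p of 0.0496 each. Of the genes past the threshold, 4 were shared with hippocampus, namely Fdft1, Sqle, Stard4 and Nsdhl. By the matching of arrays, both regions came from the same mice, so prefrontal cortex is not an independent set of animals.

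Over the 17 members of the list in prefrontal cortex, 12 rose adjusted over the list alone and 17 lay above 0. The mean difference was 0.24 (camera adjusted p = 4.83e-15; adjusted p = 0.176 with an estimated correlation), and a permutation test within treatment gave p = 0.00025 (adjusted p = 0.0015). Astrocyte markers fell, mean -0.08 with 6 of 13 lower adjusted over the list alone (camera adjusted p = 2.32e-08; adjusted p = 0.0846 with an estimated correlation). Oligodendrocyte and myelin markers fell, mean -0.11 (camera adjusted p = 1.36e-06; adjusted p = 0.567 with an estimated correlation). The number of genes depended on single arrays: leaving out any of 24 of the 32 arrays moved it by more than 1.5 times, from 3 without Tg2576 PF-04447943 replicate 2 to 10 without Tg2576 PF-04447943 replicate 7. It was 34 with arrays centred on their median, with 24 falls, and 0 in either set of replicate numbers. With signal range as a covariate, added after seeing the data, it was 52 and the list's mean was 0.16. It was 19 with replicate number as a block and 62 with numbers 1 to 4 against 5 to 8 as a block.

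**Figure D2:**
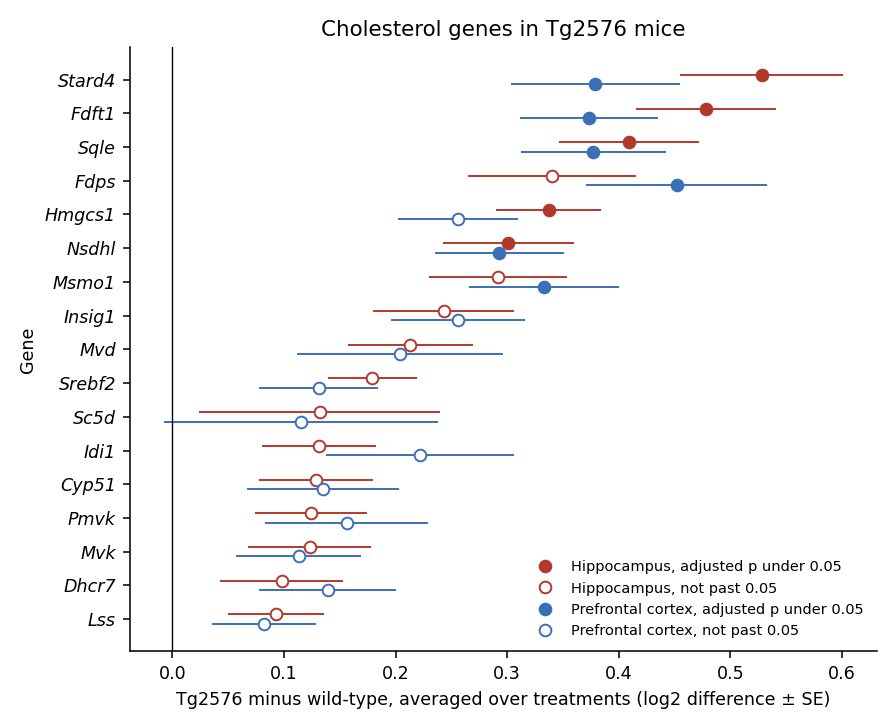
Log2 difference between Tg2576 and wild-type mice, averaged over treatments, for each of the 17 cholesterol synthesis and uptake genes in hippocampus and prefrontal cortex. Bars show 1 SE of limma to each side. All 17 lie above 0 in both regions, up to 0.53 for Stard4 in hippocampus and 0.45 for Fdps in prefrontal cortex.

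Within prefrontal cortex, neither treatment alone gave a gene past the threshold by limma. Under vehicle 1563 genes had an unadjusted p under 0.05, and the smallest p belonged to Gin1 at 0.30, Qk at -0.29 and Irf2bpl at -0.26 (limma adjusted p = 0.119). Fdft1 was at 0.40 (limma adjusted p = 0.153). The cholesterol list had a mean of 0.24 under vehicle with 9 members past the threshold adjusted over the list alone (camera adjusted p = 2.46e-08; adjusted p = 0.609 with an estimated correlation; exact permutation p = 0.00233, adjusted 0.00559). Its mean under vehicle was 0.14 with signal range as a covariate. Under vehicle 6 genes passed with replicate number as a block, and 17 with numbers 1 to 4 against 5 to 8 as a block, chosen after seeing the data. Under PF-04447943 476 genes had an unadjusted p under 0.05, against 646.3 expected by chance. Zfp189 at 0.35 and Fdps at 0.45 were among those with the smallest p. There the list's mean was 0.23 with 8 members past the threshold adjusted over the list alone (camera adjusted p = 8e-15; adjusted p = 0.185 with an estimated correlation; exact permutation p = 0.0306, adjusted 0.0612).

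The probe sets for the transgene-related genes differed little. They are probe sets of mouse genes and the transgene is of human sequence, so these values do not show whether it was expressed. App had 4 probe sets. The brightest, at log2 13.98 in Tg2576 hippocampus, differed by 0.01 ± 0.02 between genotypes (SE), and the next by 0.06 ± 0.03 in hippocampus and 0.05 ± 0.03 in prefrontal cortex. The other 2 App probe sets lay at log2 3.46 to 3.83, below the filter level of either region, and 1 of them differed by 0.04 ± 0.05 in hippocampus. The 2 Prnp probe sets differed by 0.06 ± 0.04 and -0.00 ± 0.03 in hippocampus. None passed the threshold. Pde9a differed between genotypes by 0.04 in hippocampus and 0.02 in prefrontal cortex and did not pass. With replicate numbers 1 to 4 only, chosen after seeing the data, the hippocampal difference of Pde9a turned to -0.23, and to -0.35 under vehicle, and with numbers 5 to 8 it was 0.31, none past the threshold. No gene of the list of amyloid precursor processing and clearance passed the threshold in any transgene or drug comparison by limma, and at most 4 of its 24 members had an unadjusted p under 0.05.

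Whether the transgene effect differed between regions was tested directly. No gene passed by limma, and 912 had an unadjusted p under 0.05. Usp16, a deubiquitinase, had the smallest p, at -0.10 in hippocampus and 0.06 in prefrontal cortex, a difference of -0.16 ± 0.04 (SE, adjusted p = 0.68). Dentate granule cell markers had a mean difference of -0.33 between regions (camera adjusted p = 0.00283; adjusted p = 0.953 with an estimated correlation), and -0.24 without hippocampus Tg2576 PF-04447943 replicate 1. The cholesterol list was not past the threshold in this contrast.

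What PF-04447943 alters in hippocampus was examined over both genotypes. Here 102 genes rose and 201 fell, by small amounts. The excess of falls depended on the setting: 38 rose and 25 fell with the 60th percentile filter, and 500 rose and 460 fell at an adjusted p under 0.10. In arrays numbered 1 to 4, chosen after seeing the data, 656 rose and 506 fell. The excess was wider in others, with 37 rises and 298 falls after centring on the array median, 21 and 109 with quantile normalization and 199 and 654 with no filter. Ppp3cc, a catalytic subunit of calcineurin, rose by 0.31 ± 0.07 (SE, n = 16 per treatment, adjusted p = 0.0161), above the vehicle mean of its genotype in 16 of 16 arrays. Myh7b rose by 0.33, the retromer-associated Snx6 by 0.30, Ifrd1 by 0.30, Fkbp3 by 0.30 and Polr3a, the large subunit of RNA polymerase III, by 0.29. Rdh11, Vbp1, Cetn3 and Dcaf17 rose by 0.27, 0.26, 0.26 and 0.26. Nlgn1, the adhesion protein of excitatory synapses, rose by 0.24 (adjusted p = 0.0422, 16 of 16).

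Among the falls, Slc17a2, a sodium-dependent phosphate transporter, fell by 0.37 ± 0.05 (SE, adjusted p = 0.000674, lower in 16 of 16 arrays) and Insyn2a, a protein of inhibitory synapses, fell by 0.35 ± 0.06 (SE, adjusted p = 0.00573, 16 of 16). Cyp2b10 fell by 0.52, Oprm1, the mu opioid receptor, by 0.42, Zg16 by 0.39, Spem1 by 0.39 and Igf2bp1 by 0.37. The gene 2010109A12Rik fell by 0.47 and H2-Ea, of the class II histocompatibility complex, by 0.36. Genes of inflammation were among them: Nfkb2 fell by 0.40 (adjusted p = 0.0148, 16 of 16), the chemokine Cxcl1 by 0.24 (adjusted p = 0.0191, 15 of 16) and the interferon-induced peptide transporter Tap1 by 0.30 (adjusted p = 0.015, 15 of 16).

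By list, 2 of 14 inflammatory signalling genes fell, over all genes and adjusted over the list alone (camera adjusted p = 0.0317; adjusted p = 0.957 with an estimated correlation). Of 16 interferon response genes 1 fell over all genes and 2 adjusted over the list alone (camera adjusted p = 0.0317; adjusted p = 0.993 with an estimated correlation). Ribosomal protein genes had a mean of 0.05, with 4 of 14 higher adjusted over the list alone (camera adjusted p = 0.0317; adjusted p = 0.993 with an estimated correlation). Markers of amyloid-associated microglial activation had a mean of -0.06 (camera adjusted p = 0.0317; adjusted p = 0.957 with an estimated correlation). No gene of the cyclic GMP list passed by limma, and the list's camera adjusted p was 0.745. An unadjusted p under 0.05 was found for 5 of its 23 genes, a share like that of all genes tested, 2806 of 12962. Pde9a differed by 0.08 ± 0.11 (SE, adjusted p = 0.676, higher in 10 of 16 arrays). The cholesterol list had a mean of 0.07 with treatment (permutation p = 0.0855).

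The hippocampal drug differences went with expression level and signal range. The 201 genes that fell sat at a median level percentile of 13.2 among genes tested, with 189 below the median level, and the 102 that rose sat at 61.7. Averaged over genotypes, the signal range was higher under PF-04447943 by 0.11 (permutation p = 0.00367, adjusted p = 0.022). With signal range as a covariate, added after seeing the data, 1 gene passed and none of the 303 did. The median change was then 0.11 in place of 0.18 for genes that rose and -0.12 in place of -0.24 for genes that fell. The count was 130 with quantile normalization, of which 114 belonged to the 303, and 63 with a filter at the 60th percentile. It was 743 with replicate number as a block, 799 with numbers 1 to 4 against 5 to 8 as a block, 577 with array weights and 853 with no filter. It was 1162 in arrays numbered 1 to 4 and 0 in those numbered 5 to 8, where median changes were 0.11 and -0.18. Leaving out 1 array gave from 80, without Tg2576 vehicle replicate 4, to 812, without Tg2576 vehicle replicate 8.

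**Figure D3:**
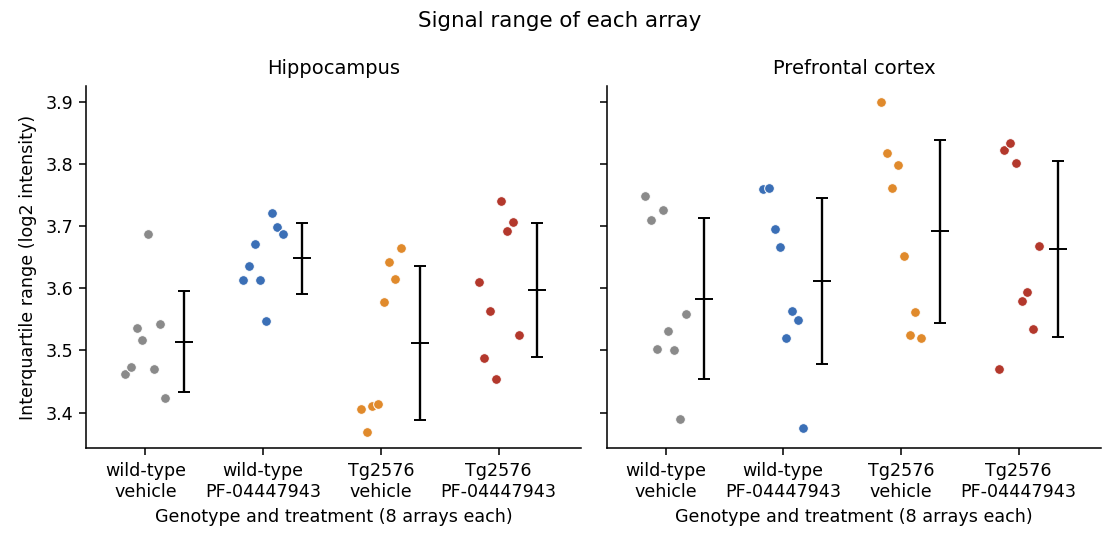
Signal range of each of the 64 arrays, the interquartile range of its log2 values, by region and group, with the group mean and SD. In hippocampus the mean was 3.51 in both vehicle groups, 3.60 in Tg2576 and 3.65 in wild-type mice given PF-04447943.

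**Figure D4:**
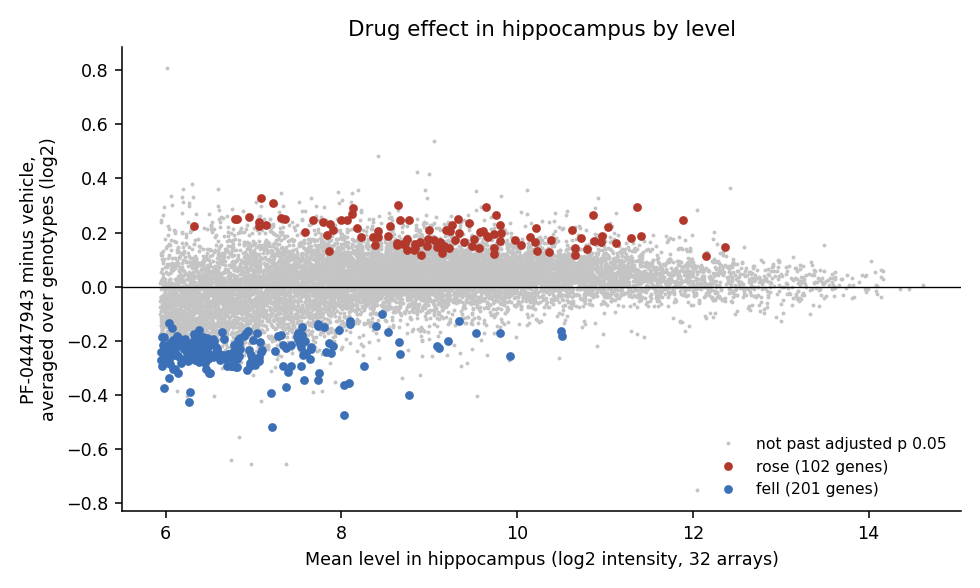
Log2 change with PF-04447943 in hippocampus, averaged over genotypes, against the mean log2 intensity of each gene tested, with the 102 genes that rose and the 201 that fell marked. Most genes that fell are at low intensity, 189 of 201 below the median level of the genes tested.

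In wild-type hippocampus alone, 5 genes fell with PF-04447943 and 0 rose, each lower in 8 of 8 arrays (SE, n = 8 per group, limma). Slc17a2 fell by 0.44 ± 0.07 (limma adjusted p = 0.0158), Insyn2a by 0.44, the potassium channel gene Kcnk16 by 0.41 (limma adjusted p = 0.0304), Cyp17a1, an enzyme of steroid hormone synthesis, by 0.32 and Lelp1 by 0.28. Choroid plexus markers had a median of -0.67 (camera adjusted p = 0.0399; adjusted p = 0.975 with an estimated correlation). Their mean was -0.64, and -0.30 without wild-type vehicle replicate 5 and -1.02 without wild-type PF-04447943 replicate 5. The count of genes was 1 with the dissection covariate, 2 with the RNA quality covariate, and 1 each with quantile normalization, all probe sets, the mean of probe sets and the trend and robust prior. It was 0 with the signal range as covariate, 0 with the stricter filter, 0 with arrays centred on their median and 0 with numbers 5 to 8 only, against 33 with numbers 1 to 4. It was 57 with no filter, 608 with array weights, 100 with only these groups in the fit, 22 with replicate number as a block and 87 with numbers 1 to 4 against 5 to 8 as a block. Leaving out 1 array gave from 0, without wild-type PF-04447943 replicate 8, to 27, without wild-type vehicle replicate 5. No gene passed in Tg2576 hippocampus by limma, where 1445 had an unadjusted p under 0.05. With arrays numbered 1 to 4 only, 89 genes passed, 66 higher and 23 lower, against 0 with numbers 5 to 8, and 8 passed without Tg2576 vehicle replicate 5. The smallest p there belonged to 2510009E07Rik at 0.28, Fam83d at -0.29 and Nufip2 at 0.30, with a limma adjusted p of 0.159. In Tg2576 mice interferon response genes had a mean of -0.12 (camera adjusted p = 0.000666; adjusted p = 0.722 with an estimated correlation).

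The drug effect was not shown to differ between genotypes in hippocampus. The interaction gave 0 genes by limma, and 361 had an unadjusted p under 0.05, against 648.1 expected by chance. Etnppl, which breaks down phosphoethanolamine and is found in astrocytes, had the smallest p at -1.56 ± 0.42 (SE, adjusted p = 1). Its means were 7.86 under vehicle and 7.06 under PF-04447943 in Tg2576 mice, and 7.10 and 7.85 in wild-type mice. Microglial markers had a mean interaction of -0.13 (camera adjusted p = 0.00684; adjusted p = 0.909 with an estimated correlation), and -0.081 without Tg2576 vehicle replicate 6. Across the 12962 genes, which are not independent replicates, the drug effects in both genotypes had a correlation of 0.36 (permutation p = 0.1 from 100 permutations of treatment), and with no filter 0.398 (permutation p = 0.03).

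In prefrontal cortex PF-04447943 changed 1 gene over both genotypes. Ctcf, the factor that organises chromatin loops, rose by 0.20 ± 0.03 (SE, n = 16 per treatment, adjusted p = 0.019), in 16 of 16 arrays. Its means were 9.44 and 9.64 in Tg2576 and 9.41 and 9.61 in wild-type mice under vehicle and drug. The call ended with quantile normalization, with centring on the array median, with all probe sets tested, and with the mean of the Ctcf probe sets, where the difference was 0.09. By limma 301 genes had an unadjusted p under 0.05, against 646.3 expected by chance. Nlgn1 lay at 0.18 ± 0.05 (SE, adjusted p = 1), Rbm39 at -0.15 and Pde9a at -0.07 ± 0.05 (SE, adjusted p = 1).

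Marker lists in prefrontal cortex moved with the drug at the preset correlation, and none with an estimated one. Oligodendrocyte and myelin markers fell, with a mean of -0.12 and 1 of 14 above 0 (camera adjusted p = 9.83e-06; adjusted p = 0.876 with an estimated correlation). Microglial markers fell, mean -0.07 (camera adjusted p = 0.000201; adjusted p = 0.876 with an estimated correlation), and activity-regulated immediate early genes fell, mean -0.14 (camera adjusted p = 0.0016; adjusted p = 0.876 with an estimated correlation). Inhibitory neuron markers rose, mean 0.07 (camera adjusted p = 0.00199; adjusted p = 0.696 with an estimated correlation). No member of these 4 lists passed over all genes or adjusted over the list alone by limma, and 0, 2, 4 and 2 had an unadjusted p under 0.05. Neither genotype alone gave a gene past the threshold in prefrontal cortex. By limma 389 genes in Tg2576 and 327 in wild-type mice had an unadjusted p under 0.05, against 646.3 expected by chance. Src lay at 0.47 in Tg2576 mice (limma adjusted p = 0.999) and Slc16a6 at 0.37 in wild-type mice (limma adjusted p = 1). The interaction gave 0 genes by limma, with 429 at an unadjusted p under 0.05 and Grik3, a kainate receptor subunit, at 0.63 ± 0.16 (SE, adjusted p = 1).

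The drug effect differed between regions for 1 gene. Slc17a2 changed by -0.37 in hippocampus and 0.06 in prefrontal cortex, a difference of -0.43 ± 0.08 (SE, adjusted p = 0.0109). Insyn2a at -0.35 and 0.01 missed the threshold (adjusted p = 0.0578), as did Mir142 and Clspn at differences of -0.31 and -0.32. Each array entered this test as an independent sample. With mice matched between regions, chosen after seeing the data, as a random block, Slc17a2 passed (adjusted p = 0.00838) and Insyn2a, Mir142 and Clspn did too (adjusted p = 0.044 each). With the difference taken per matched mouse, the call for Slc17a2 ended at the same size of -0.43 ± 0.09 (SE, adjusted p = 0.0551) and Ccdc39 passed at 0.34 ± 0.06 (SE, adjusted p = 0.0234). It was the only gene past the threshold there, so Insyn2a, Mir142 and Clspn did not pass. The call for Slc17a2 also ended with the 60th percentile filter, with the mean of probe sets and with the difference per replicate number (adjusted p = 0.0647). The count was 49 with no filter, 122 with array weights, 8 with all probe sets, 8 with arrays centred on their median and, chosen after seeing the data, 50 with numbers 1 to 4 against 5 to 8 as a block and 3 with signal range as a covariate. By limma 1258 genes had an unadjusted p under 0.05. Leaving out any of 18 of the 64 arrays gave 2 or more genes, up to 10 without hippocampus Tg2576 PF-04447943 replicate 4. For 6 of the 8 Tg2576 mice given PF-04447943, the same replicate number did not mark matching arrays in both regions.

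Whether the drug moved expression in Tg2576 mice against the transgene effect was examined across genes, which are not independent replicates. In hippocampus the drug effect in Tg2576 mice and the transgene effect under vehicle had a correlation of -0.42 over 12962 genes. Both effects share the Tg2576 vehicle arrays, and 100 simulations of unchanged groups gave a mean of -0.48, from -0.75 to -0.18. With the shared arrays split into sets of 4, the mean over 35 splits was -0.037. In prefrontal cortex the correlation was -0.51, against -0.50 in simulations and -0.022 with split arrays. The mean of the cholesterol list in Tg2576 hippocampus was 9.49 under vehicle and 9.55 under PF-04447943, a difference of 0.06 (exact permutation p = 0.315, adjusted 0.42).

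The regional difference in vehicle-treated wild-type mice gives a scale for these effects. Of 12951 genes, 2735 were higher in hippocampus and 3085 higher in prefrontal cortex. Markers of CA1 and CA3 pyramidal cells were higher in hippocampus, 11 of 12 members past the threshold over all genes and adjusted over the list alone (camera adjusted p = 9.08e-09; adjusted p = 0.0335 with an estimated correlation). Fibcd1, a marker of CA1, was higher by 3.51, and the dentate gyrus genes Dsp and C1ql2 by 4.75 and 3.57. The calcium-binding protein gene Cabp7 was higher by 3.66 and Shisa6, an auxiliary subunit of AMPA receptors, by 3.47. The deep layer transcription factor Foxp2 fell by 2.50 from prefrontal cortex to hippocampus, Cux2, of upper layers, fell by 2.29 and Tbr1, of deep layers, fell by 1.63. The muscle-type genes Myl4 and Tnnc1 differed by -3.55 and -2.78.

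Other cell types differed between regions as well. Of 15 oligodendrocyte and myelin markers 13 were higher in hippocampus (camera adjusted p = 0.000254; adjusted p = 0.567 with an estimated correlation), as were 6 of 7 choroid plexus and 7 of 8 ependymal markers (camera adjusted p = 0.00415 and 0.00533; adjusted p = 0.567 with an estimated correlation for both). The choroid plexus gene Ttr, which carries thyroid hormone, was 12.84 ± 2.14 in hippocampus (SD, n = 8) and higher there than in prefrontal cortex, with its brightest array at the highest value deposited, so that no size of the difference is given. Of 18 circadian clock genes 12 were lower in hippocampus (camera adjusted p = 0.00415; adjusted p = 0.428 with an estimated correlation). In the cholesterol list 10 of 17 genes were lower in hippocampus and 1 higher (camera adjusted p = 0.0115; adjusted p = 0.771 with an estimated correlation), with Stard4 at -0.81. Of all list calls, those that held with an estimated correlation were the cholesterol list in hippocampus under vehicle and over both treatments, and CA1 and CA3 pyramidal cells in the regional difference.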

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

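The tests of signal range, of oligodendrocyte and astrocyte markers as a source of the cholesterol signal, and of the matching of arrays between regions were chosen only after the results were seen. The tests of a strain variant and of liver X receptor targets were added after the data had been examined but before their own results, and the others in this part were planned.

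Genes of cholesterol synthesis and uptake were higher in Tg2576 mice in both regions, with 17 of 17 members above 0 in each and 5 in hippocampus and 6 in prefrontal cortex past the threshold over all genes (adjusted p = 0.0038 with an estimated correlation in hippocampus; adjusted p = 0.176 with an estimated correlation in prefrontal cortex, where the list call was lost). Signal range of the arrays as the whole cause is argued against for the averages over both treatments. With it as a covariate the list's mean there kept 68.7% or more of its size, 0.26 in hippocampus and 0.16 in prefrontal cortex. In these fits 10 and 7 members passed the threshold. The rule was set after the results were seen, and the prefrontal cortex value lay close to its limit. Under vehicle in prefrontal cortex the mean went from 0.24 to 0.14, so signal range as part of the cause stays open there. The 7 members past the threshold in either region lie on 7 chromosomes, so they cannot all be neighbours of the transgene insertion. They come from a pathway list whose members lie on many chromosomes, so this outcome was largely set by the list. It does not decide on a strain variant beside the insertion, and a linked variant of a regulator was not tested. A larger share of oligodendrocytes or astrocytes is argued against, since the highest mean among both marker lists and both regions was -0.078. The permutation p in hippocampus and prefrontal cortex was 0.124 and 0.192 for oligodendrocyte markers. For astrocyte markers it was 0.00599 and 0.0367 (adjusted 0.0719 and 0.147), so a fall of either list is not established. The genotype may have raised sterol synthesis, a hypothesis found and tested on the same data, from the same matched mice in both regions. Lower sterol sensing through liver X receptors cannot be told apart from other causes, because their targets had a mean of -0.011 at most (permutation p = 0.708 in prefrontal cortex and 0.372 in hippocampus).

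The hippocampal genes changed by PF-04447943 over both genotypes, 102 higher and 201 lower, moved with the signal range of the arrays. With signal range as a covariate 0 of the 303 passed, because the median change shrank from 0.18 to 0.11 and from -0.24 to -0.12 while the median standard error went from 0.05 to 0.05 and from 0.06 to 0.05. Yet 114 of the 303 passed after quantile normalization, which makes the distributions of the arrays equal, and signal range differed with treatment, so an effect of PF-04447943 and a difference in array signal cannot be told apart for these genes. Choroid plexus or other tissue in the dissection could account for part of the genes and stays open, since 167 of 303 passed with its covariate, and the level of Ttr, a choroid plexus marker, spread by an SD of 2.14 between hippocampal arrays of vehicle-treated wild-type mice, up to the highest value deposited. RNA quality as the cause is argued against, because 254 of 303 passed with its covariate.

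The same replicate number did not mark the same mouse in hippocampus and prefrontal cortex in every group. Among 23 probe sets with 2 separate levels in both regions, which tell mice apart, the best match of 26 of 32 hippocampal arrays had their own number, at a correlation across probe sets of at least 0.84. The other 6 were numbers 1 to 6 of Tg2576 mice given PF-04447943, whose best matches carried the numbers 2, 3, 4, 5, 6 and 1. Their best correlations were at least 0.905 while those with their own number ran from -0.311 to 0.751. Arrays exchanged between groups in 1 region are argued against, as 0 of 32 matched best in another group, a mouse misplaced in both regions would go unseen, and no biological explanation was tested.

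Of 108 groups of samples tested, 8 held a sample far from the others of its group, and chance gives about 1 in 20, or 5.4. The signal range of wild-type vehicle replicate 5 in hippocampus was 3.69, above the rest of its group. In hippocampal Tg2576 PF-04447943 replicate 1, Fdft1 at 10.96, Stard4 at 9.05 and Hmgcs1 at 12.8 were far above their group, and Tlr3 at 6.98 was far below. Xist was 11.65 in hippocampal wild-type PF-04447943 replicate 5, below its group. Sqle was 9.82 in prefrontal cortex Tg2576 PF-04447943 replicate 6, below its group. Pde9a was 8.11 in prefrontal cortex wild-type vehicle replicate 5, above its group.

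Some effects differed between regions or genotypes in a test of the difference. For the drug effect by region, hippocampus minus prefrontal cortex, the value was -0.43 for Slc17a2. That call ended with the difference taken per matched mouse (limma adjusted p = 0.0551). Olfactory bulb markers were at -0.22 (adjusted p = 0.992 with an estimated correlation, and a mean of -0.063 without prefrontal cortex wild-type PF-04447943 replicate 8). The other values were -0.08 for the inflammatory signalling list (adjusted p = 0.537 with an estimated correlation) and 0.06 for ribosomal protein genes (adjusted p = 0.992 with an estimated correlation). For the transgene effect by region they were -0.33 for dentate granule cell markers (adjusted p = 0.953 with an estimated correlation), 0.04 for presynaptic vesicle release (a mean of 0.02 without hippocampus Tg2576 PF-04447943 replicate 1 and 0.06 without prefrontal cortex wild-type vehicle replicate 5) and -0.06 for ribosomal protein genes (adjusted p = 0.963 with an estimated correlation for both). Without hippocampus Tg2576 PF-04447943 replicate 1 the mean of the dentate granule cell markers was -0.24. The microglial markers differed by -0.13 in the drug by genotype interaction in hippocampus (adjusted p = 0.909 with an estimated correlation). Among probe sets with no gene symbol here, which the comparisons left out, 2 rose in Tg2576 hippocampus, by 0.47 and 0.32, and 2 rose in Tg2576 prefrontal cortex, by 0.32 and 0.20.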

How the results depend on the processing

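The signal range covariate, the fits of replicate numbers 1 to 4 or 5 to 8, the fits on matched mice, list means with each array left out, and the block of replicate numbers 1 to 4 against 5 to 8 were chosen after seeing the data, and the other alternatives were planned. The cholesterol list kept its direction in all settings and in every fit that left out an array, with means over both treatments from 0.17 to 0.31 in hippocampus and from 0.16 to 0.26 in prefrontal cortex. Of 3217 values of named genes under alternatives, 2969 kept their direction and side of the threshold, 181 lost the threshold, 64 gained it and 3 turned. These values include large regional differences and genes that did not pass in the main fit, which keep their side easily. The share therefore says little about the drug and transgene calls. Counts of genes moved more, and the cause was not tested. Fewer genes or arrays entered with a stricter filter or with part of the replicate numbers, yet some counts rose there. Arrays give no depth, and background signal limits the genes near the filter level. A sex covariate was not run. Within a region, the same number in different groups marks different mice, and 0 of 12 pairs of groups had all same-number correlations of deviations over all genes above 0.1. Across regions 0 of 4 groups had them all above 0.1, although the numbers mark the same mouse for 26 of 32 arrays by the transcripts with 2 levels. Arrays of the same number as a random block over both regions, which joins different mice in 6 of 32 cases, had a correlation of -0.022, and matched mice had 0.033.

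The main counts were, in hippocampus, 1 gene for the transgene under vehicle, 0 for the transgene under PF-04447943, 0 for the drug in Tg2576 mice, 5 for the drug in wild-type mice, 303 for the averaged drug effect and 12 for the averaged transgene effect. In prefrontal cortex they were 0 for the transgene under either treatment, 1 for the averaged drug effect and 6 for the averaged transgene effect. They were 1 for the drug effect by region and 5820 for the regional difference. By limma, 2735 of those 5820 were rises, and the alternatives below are counts of genes past the threshold.

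With no filter, the drug in wild-type hippocampus gave 57, the averaged hippocampal drug effect 853, the averaged transgene effect in prefrontal cortex 3 and the drug effect by region 49. With the 60th percentile filter, the hippocampal transgene effect under PF-04447943 gave 2, the drug in wild-type hippocampus 0, the averaged drug effect 63, with 38 rises, the averaged transgene effect 20 and the drug effect by region 0. With all probe sets, the hippocampal transgene effect under vehicle gave 3, the drug in wild-type hippocampus 1, the averaged drug effect 589, the averaged transgene effect 26, the averaged drug effect in prefrontal cortex 0, the drug effect by region 8 and the regional difference 10934. With the mean of probe sets, the drug in wild-type hippocampus gave 1, the averaged hippocampal drug effect 115, the averaged hippocampal transgene effect 8, with 6 rises, the transgene effect in prefrontal cortex under vehicle 1, the averaged drug effect there 0 and the drug effect by region 0, and Laptm5 turned to 0.046 in the regional difference.

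With quantile normalization, the hippocampal transgene effect gave 2 under vehicle and 2 under PF-04447943, the drug in wild-type hippocampus 1 and the averaged drug effect 130, with 21 rises. In prefrontal cortex it gave 3 for the transgene under vehicle, 0 for the averaged drug effect and 16 for the averaged transgene effect, with 8 rises. With median centring, the hippocampal counts were 3 and 1 for the transgene under vehicle and PF-04447943, 0 for the drug in wild-type mice and 335 for the averaged drug effect, with 37 rises. It gave 0 for the averaged drug effect and 34 for the averaged transgene effect in prefrontal cortex, and 8 for the drug effect by region. With the trend and robust prior, the transgene under PF-04447943 gave 2 in hippocampus and the drug in wild-type mice 1.

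With array weights, the hippocampal counts were 3 and 2 for the transgene under vehicle and PF-04447943, 608 for the drug in wild-type mice, 577 for the averaged drug effect and 25 for the averaged transgene effect. In prefrontal cortex they were 29 and 1 for the transgene under vehicle and PF-04447943, 2 for the averaged drug effect and 31 for the averaged transgene effect, and the drug effect by region gave 122. With the dissection covariate, hippocampus gave 2 for the transgene under vehicle, 1 for the drug in wild-type mice and 170 for the averaged drug effect, and prefrontal cortex 10 for the averaged transgene effect. With the RNA quality covariate, the drug in wild-type hippocampus gave 2 and the averaged transgene effect in prefrontal cortex 16. With the signal range covariate, hippocampus gave 2 for the transgene under PF-04447943, 0 for the drug in wild-type mice, 1 for the averaged drug effect and 25 for the averaged transgene effect. Prefrontal cortex gave 11 and 2 for the transgene under vehicle and PF-04447943 and 52 for the averaged transgene effect, with 43 falls, and the drug effect by region 3.

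With replicate number as a block, hippocampus gave 2 and 2 for the transgene under vehicle and PF-04447943, 22 for the drug in wild-type mice and 743 for the averaged drug effect, and prefrontal cortex 6 for the transgene under vehicle and 19 for the averaged transgene effect. For the drug effect by region, the difference per replicate number, which joins different mice in 6 of 32 cases, gave 0. Matched mice as a random block gave 4, and the difference per matched mouse 1. With numbers 1 to 4 against 5 to 8 as a block, the drug gave 87 in wild-type hippocampus and 799 averaged, the transgene in prefrontal cortex 17 under vehicle and 62 averaged, and the drug effect by region 50. Fits of only the compared groups gave 2 for the hippocampal transgene under vehicle and 100 for the drug in wild-type hippocampus. At an adjusted p under 0.10, the hippocampal transgene under PF-04447943 gave 2, the drug in wild-type mice 21, the averaged drug effect 960, with 500 rises, the averaged transgene effect 22 and the drug effect by region 13.

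With numbers 1 to 4 only, hippocampus gave 0 and 1 for the transgene under vehicle and PF-04447943, 89 for the drug in Tg2576 mice, 33 for the drug in wild-type mice, 1162 averaged, with 656 rises, and 6 for the averaged transgene effect. Prefrontal cortex gave 1 for the transgene under vehicle, 0 for the averaged drug effect and 0 for the averaged transgene effect. The cholesterol mean in hippocampus under vehicle was 0.11, and Pde9a turned to -0.35 under vehicle and -0.23 averaged for the transgene. With numbers 5 to 8 only, hippocampus gave 9 for the transgene under vehicle and 0 for the drug in wild-type mice and averaged, prefrontal cortex 0 for both averaged effects, and the cholesterol mean was 0.40.

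Lists past the threshold, at the preset correlation, with an estimated one and by fry, numbered 6, 1 and 1 for the hippocampal transgene under vehicle, 9, 0 and 1 under PF-04447943 and 9, 1 and 1 averaged. The drug in hippocampus gave 2, 0 and 0 in Tg2576 mice, 4, 0 and 0 in wild-type mice, 5, 0 and 0 averaged, and 1, 0 and 0 for the interaction. In prefrontal cortex the transgene gave 4, 0 and 0 under vehicle, 6, 0 and 0 under PF-04447943 and 6, 0 and 1 averaged. The drug there gave 4, 0 and 0 in Tg2576 mice, 2, 0 and 0 in wild-type mice and 7, 0 and 0 averaged. The drug and transgene effects by region gave 3, 0 and 0 each, and the regional difference 12, 1 and 22. With no filter, the drug in hippocampus gave 1 list in wild-type mice, 8 for the interaction and 2 averaged, and in prefrontal cortex 2 in Tg2576 and 4 in wild-type mice, and the averaged transgene effect there 3. The correlation of drug and transgene effects was -0.037 in hippocampus and -0.022 in prefrontal cortex with split vehicle arrays, and that of the drug effects of both genotypes in hippocampus was 0.40 with no filter (0.398, permutation p = 0.03 against 0.1).

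Leaving out 1 array, the counts ran in hippocampus from 1 to 8 for the transgene under vehicle, from 0 to 2 under PF-04447943, from 7 to 21 averaged, from 0 to 8 for the drug in Tg2576 mice (8 without Tg2576 vehicle replicate 5, 1 without replicate 8), from 0 to 27 in wild-type mice and from 80 to 812 averaged. In prefrontal cortex they ran from 0 to 3 for the transgene under vehicle (3 without Tg2576 vehicle replicate 6) and from 3 to 10 averaged. The drug effect by region ran from 1 to 10, or from 2 in the fits that moved it. Means of lists ran, in hippocampus, from -0.21 to -0.086 for oligodendrocyte and myelin markers with the averaged transgene effect, from 0.026 to 0.065 for microglial markers there and from -0.15 to -0.081 for their interaction. Choroid plexus markers ran from -0.97 to -0.39 for the transgene under vehicle and from -1.02 to -0.30 for the drug in wild-type mice, and presynaptic vesicle release from 0.02 to 0.06 for the transgene effect by region.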

Other observations

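The comparison of signal range between replicate numbers 1 to 4 and 5 to 8 was chosen only after the result was seen, as were the splits balanced over these numbers, while the random splits of the samples were planned.

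Other members of the fixed lists also differed between regions in vehicle-treated wild-type mice, some higher in hippocampus and some in prefrontal cortex. Nr3c2, the mineralocorticoid receptor, was higher in hippocampus by 2.08, Prkcd by 1.95, Cebpd by 2.41 and Gfap, the filament protein of astrocytes, by 2.31. Higher in prefrontal cortex were the inhibitory neuron markers Vip and Pvalb, which differed by -1.52 and -0.81, the neuropeptide genes Crh and Tac1 by -2.18 and -1.63, and Gucy1a1, a subunit of the nitric oxide receptor that makes cyclic GMP, by -1.75. Tac1 is also a striatal marker of the fixed lists. The mean standardised level of those markers ran from -0.80 to 1.94 among these prefrontal cortex arrays, and the share of dissection in such differences was not tested. Among phosphodiesterases, Pde7b differed by -1.74.

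Within groups, the arrays of prefrontal cortex varied along 1 main direction. The leading component took 44.8% of the variance within groups in prefrontal cortex and 22.9% in hippocampus. In all 4 groups of prefrontal cortex the mean signal range was higher for replicate numbers 1 to 4, from 3.67 to 3.82, than for numbers 5 to 8, at most 3.59. In all 4 groups of hippocampus it was lower for numbers 1 to 4, from 3.40 to 3.63, than for numbers 5 to 8 of the same group, from 3.53 to 3.67. Exactly 4 arrays shared their highest value with an array of the other region, and 0 pairs of arrays had identical values.

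Regrouping the samples at random 100 times, the real grouping included, tested whether chance gives as many genes. For the averaged drug effect in hippocampus 1 of 100 splits gave as many genes as the real 303 and the highest other gave 0, and for the drug in wild-type hippocampus 1 of 100 gave as many as the real 5, with 0 in the highest other. For the averaged drug effect in prefrontal cortex 1 of 100 gave as many as the real 1, with 0 in the highest other, and for the averaged transgene effect there 1 of 100 gave as many as the real 6, again with 0. The regional difference gave 5820 against 1794 in the highest other split, so 1 of 100. For the averaged transgene effect in hippocampus 2 of 100 splits gave as many as the real 12. For each of these comparisons taken singly few splits gave as many genes, 1 of 100 being the least these splits can give. This argues against a grouping by chance but does not exclude it, since many comparisons were tested. For the averaged transgene effect in hippocampus the highest other split gave 1340 genes. For the prefrontal cortex drug effect chance stays open. There the call was for Ctcf alone, 301 genes had an unadjusted p under 0.05 against 646 expected by chance, and the difference was 0.09 with the mean of the Ctcf probe sets. Balanced splits gave the same shares for these 6 comparisons, with the highest other at 4 for the drug in wild-type hippocampus, 110 for the averaged transgene effect there, 3 for it in prefrontal cortex and 3734 for the regional difference.

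For 2 other comparisons more of the planned splits gave as many genes, and chance stays open there too. The transgene effect under vehicle in hippocampus, with 1 gene, was matched in 6 of 100 splits, the highest with 543, and the drug effect by region, with 1 gene, in 9 of 100, the highest with 85. Those splits pass over the shift of signal range between replicate numbers 1 to 4 and 5 to 8, while the real groups hold 4 arrays of each. With splits that keep this balance the shares were 4 of 100, the highest with 45, and 2 of 100, the highest with 1, so whether chance gave these single genes depends on how the samples are regrouped and stays open. Where the real split gave 0 genes, any split gives as many, 100 of 100, so the splits test nothing there. The highest others were then 967, 690 and 205 in hippocampus for the transgene under PF-04447943, the drug in Tg2576 mice and the interaction. In prefrontal cortex they were 2, 1, 4276, 2 and 9 for the transgene under vehicle and under PF-04447943, the drug in Tg2576 mice, the drug in wild-type mice and the interaction, and 0 for the transgene effect by region. Splits with 4276, 967 or 690 genes, and 1 with 1340 for the averaged transgene effect in hippocampus, point to a structure of the samples that follows neither genotype nor treatment.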
